A study of Paralichthys olivaceus with 2 samples.

How the data were processed

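Poly(A)-selected RNA from whole flounder larvae at 42 DAH was sequenced as Illumina paired-end reads, per the labels' protocols. There was 1 control library and 1 T3 library. The labels also describe larvae treated with T4 and with thiourea, which were not analysed here. Whether a library pooled several larvae is not given in the sources used here.

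The deposited table gives, per the file headers, a raw read count and an FPKM value per gene and library. TopHat2 2.0.12, HTSeq 0.6.1 and edgeR (no version) are named in the submitters' processing notes, without the step each served, the genome build or the annotation. Whether counting used strand is not given either, and genes that share reads with near-identical copies could not be recognised. The 2 count columns and 2 FPKM columns were matched to the samples by title, and 0 further columns of sample values were left unused.

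The scale of the deposited FPKM was tested on the file. For each of the 20038 genes with an FPKM above 0, the length in nt implied by the count, the deposited FPKM and the library's own total count was a whole number (tolerance 0.05). It was the same in both libraries for 100% of the 19019 genes detected in both. All of these numbers shared the common divisor 9, and after division by 9 all but 1 gene gave a multiple of 3, with a median of 1335 nt and a range of 93 to 102705 nt. These values are called coding lengths here. They rest on reading the factor 9 as part of the FPKM scale, which no label states; the deposited FPKM are then 9 times lower than counts per kilobase of coding sequence per 1000000 counts. The factor is common to both libraries and leaves ratios of counts, or of FPKM with nothing added, unaffected. On the log2(FPKM + 1) and log2(FPKM + 0.1) scales it does matter, since the added value weighs more on lower FPKM.

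None of the 21787 gene IDs (0 matched) occurred in the reference table of 30478 flounder genes (assembly ASM2471397v2). No member of the 27 gene lists fixed beforehand (thyroid axis, pigment cells, muscle, blood, digestive organs and others) could therefore be identified by ID. None of the lists gave a result, and their genes may be present under unnamed IDs. For the same reason the rule for named genes reduced to its stated fallback, the 2 IDs with the highest and the 2 with the lowest ratio, ranked by the interval bound nearest to equal abundance among genes with at least 50 counts. Other single genes are described by rank and coding length and were chosen after their values were seen. The lists, this rule, the scaling, the count minimum, the 2-fold rule and the alternatives listed at the end were fixed before the data were examined.

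Counts were scaled between the libraries with the trimmed mean of M-values (TMM; edgeR 4.0.16 under R 4.3.3), with factors of 1.02 for the control and 0.976 for the T3 library. Scaled CPM are counts per 1000000 of the resulting effective library size. Genes with at least 10 counts over both libraries were compared (17301), and 4486 were left out. No model with replicate variation could be fitted to 1 library per group, so no p-value is given. Instead, the exact 95% Clopper-Pearson interval of the T3 share of a gene's counts was turned into a scaled ratio (Python 3.11.15, scipy 1.17.1). A gene counted as higher when the lower bound exceeded 2-fold and as lower when the upper bound lay beyond 2-fold in the other direction. Log2 ratios were computed with 0.5 added to each scaled count. A count of 0 was taken to allow 3 counts in that library. Read pairs are not known to be independent molecules, so intervals and floors cover counting error only and leave out the variation between fish.

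The procedure was tested on simulated Poisson counts drawn at the real genes' means and library sizes for the T3 versus control comparison. With no gene changed, 0 of 17255 tested genes were called. With 200 genes of at least 50 counts changed, 65.5% were recovered at 3-fold (17246 genes tested), 93.5% at 4-fold (17235 genes) and 100% at 8-fold (17227 genes). Among the unchanged genes of these 3 runs, 3, 2 and 1 were called. The simulation holds no variation between animals. Counts were drawn and called with the same effective library sizes, so it tests the interval under counting error and not the scaling.

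Alternatives were library totals, DESeq2 1.42.0 size factors, upper-quartile scaling, totals without the 20 most abundant genes, no count minimum or one of 50, other fold limits, the point ratio without its interval, and the deposited FPKM on the log2(FPKM + 1) and log2(FPKM + 0.1) scales.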

Results

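Whole-body RNA of Japanese flounder (Paralichthys olivaceus) larvae was profiled at 42 days after hatching (DAH). The flounder is a flatfish whose larval metamorphosis is driven by thyroid hormone. One group had been given 3,3′,5-triiodo-L-thyronine (T3), the active thyroid hormone, at 0.01 mg/L for 10 days from 16 DAH, so that sampling fell 16 days after the treatment ended. The other group was untreated. Each group started with 1000 larvae and is represented by 1 library. The labels state that sequencing was done at the age at which body colour differed most between the treatment groups, and the comparison asks which genes differed in abundance between T3-treated and untreated fish at that age. With 1 library per group the difference has no replicate check, and every interval of a gene's ratio or share covers counting error only. The values therefore compare these 2 libraries, not the conditions.

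The control library held 4943675 gene counts and the T3 library 6042338, a depth ratio of 1.22. Of 21787 listed genes, 19489 had at least 1 count in the control library and 19568 in the T3 library, and 1749 had none in either. The median gene had 27 counts in the control library and 32 in the T3 library. The table identifies genes by serial IDs that are not paired with names in the sources used here, so genes are described by ID, abundance and coding length. Across the 17301 genes with at least 10 counts over both libraries, the correlation of log2 CPM (counts per 1000000) between the libraries was r = 0.95 (Pearson) and 0.94 (Spearman, on counts). These are correlations across genes, which are not independent replicates.

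Among these 17301 genes, 79 were higher in the T3 library by more than 2-fold beyond counting error, and 158 were lower by more than 2-fold. The higher genes had a median log2 ratio (T3 over control) of 1.70, and the lower genes a median of -1.90. With genes at 0 counts in the lower library placed at a floor of 3 counts in that library, the medians were 1.60 and -1.87. The higher genes together made up 2.35% of the control counts and 6.08% of the T3 counts. The lower genes made up 1.86% of the control counts and 0.559% of the T3 counts. The counting interval lay wholly beyond 4-fold for 7 higher and 9 lower genes. No p-value can be given for any of these genes. The split between higher and lower genes depended on the calling rule and on scaling. By the point ratio, without its interval, 993 genes were more than 2-fold higher and 1065 more than 2-fold lower. With the interval, the split was 66 to 187 with library totals and 98 to 129 with the 20 most abundant genes left out of the scaling.

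**Figure D1:**
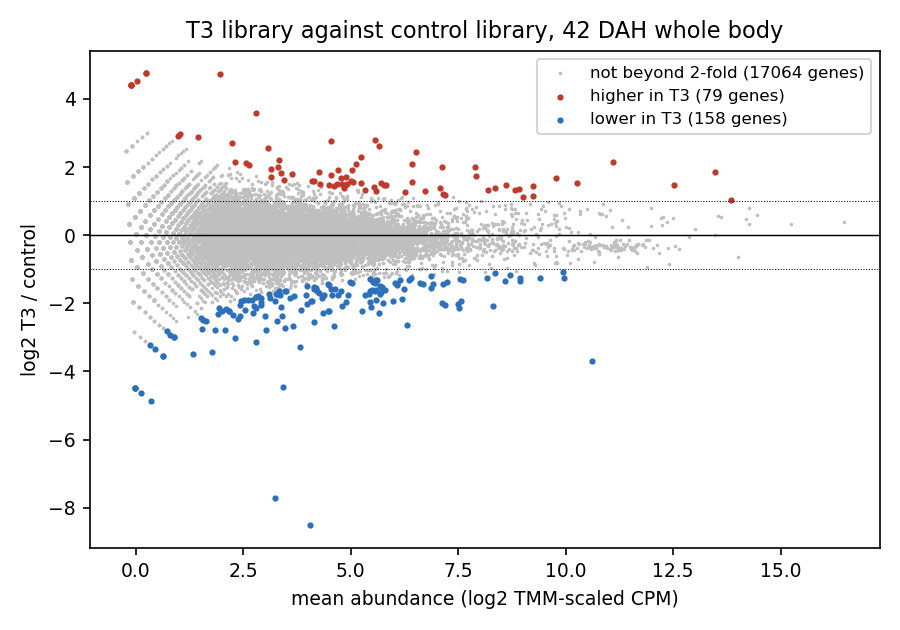
Log2 ratio of the T3 library to the control library (y axis, 0.5 added to each scaled count) against mean abundance (x axis, log2 of CPM scaled by the trimmed mean of M-values), 1 point per gene with at least 10 counts. Red points are the 79 genes higher and blue points the 158 genes lower by more than 2-fold beyond counting error, dotted lines mark 2-fold, and a dense band of abundant genes lies just below the line of equal abundance.

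Ranked by the interval bound nearest to equal abundance among genes with at least 50 counts, the first 2 genes in each direction had between 81 and 553 counts over both libraries. GS_017007, with a coding length of 921 nt, was at 11.8 scaled CPM in the control library (60 counts) and 83.6 in the T3 library (493 counts). That is 7.06-fold higher, with a 95% counting interval of 5.39 to 9.39. GS_002650 (642 nt) was at 0.987 scaled CPM in the control library (5 counts) and 12.9 in the T3 library (76 counts). It was 13.1-fold higher, with an interval of 5.36 to 41.4 that reflects the 5 control counts. In the opposite direction, GS_000805 (384 nt) had 169 counts in the control library, or 33.4 scaled CPM, and 0 in the T3 library. A count of 0 there allows up to 0.509 scaled CPM, which is 65.6-fold below the control value, and by its counting interval the gene was at least 52.7-fold lower in the T3 library. GS_011015 (630 nt) had 96 counts in the control library (19.0 scaled CPM) and 0 in the T3 library. That floor lies 37.2-fold below the control value, and by the interval the gene was at least 29.7-fold lower. Genes with 0 counts in a single library and at least 10 in the other numbered 7 in each direction, but their sizes were unequal. Where the control library had 0, the T3 library had at most 14 counts. Where the T3 library had 0, the control library had up to 169.

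Much larger shares of the counts changed in a few abundant genes. Scaled CPM are relative values for whole-body RNA and do not measure transcript amounts per cell or tissue. The 3 higher genes with the most counts ranked 8, 12 and 17 by mean share of the counts of the 2 libraries. The gene of rank 12 (1002 nt) was at 4959 scaled CPM in the control library and 17901 in the T3 library, 3.61-fold higher (interval 3.56 to 3.66). The gene of rank 17 (1305 nt) was 2.76-fold higher (2.71 to 2.81), and that of rank 8 (792 nt) 2.05-fold higher (2.03 to 2.07). The last of these stayed under 2-fold when scaled by library totals. The lower gene with the most counts (2322 nt) had 14739 counts in the control library and 1313 in the T3 library. It was 13.1-fold lower (12.3 to 13.8), whereas the next most abundant lower gene (276 nt) was 2.38-fold lower (2.29 to 2.48).

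The T3 library was more strongly dominated by its most abundant transcripts. The gene with the most counts, the same in both libraries and 1134 nt long, took 8.03% of the control counts (95% Wilson interval 8.004 to 8.052) and 10.07% of the T3 counts (10.04 to 10.09). The 20 most abundant genes of each library took 30.4% of the control counts (30.4 to 30.5) and 37.8% of the T3 counts (37.8 to 37.9). The first 50% of all counts was reached with 82 genes in the control library and 60 genes in the T3 library. Of the 20 genes with the highest mean share, 13 were higher in the T3 library beyond counting error and 6 lower, and 1 had an interval that included equal abundance. No lower one was beyond 2-fold. By the point ratio 14 were higher, against 13 with library totals and 15 with the 20 genes left out of the scaling.

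**Figure D2:**
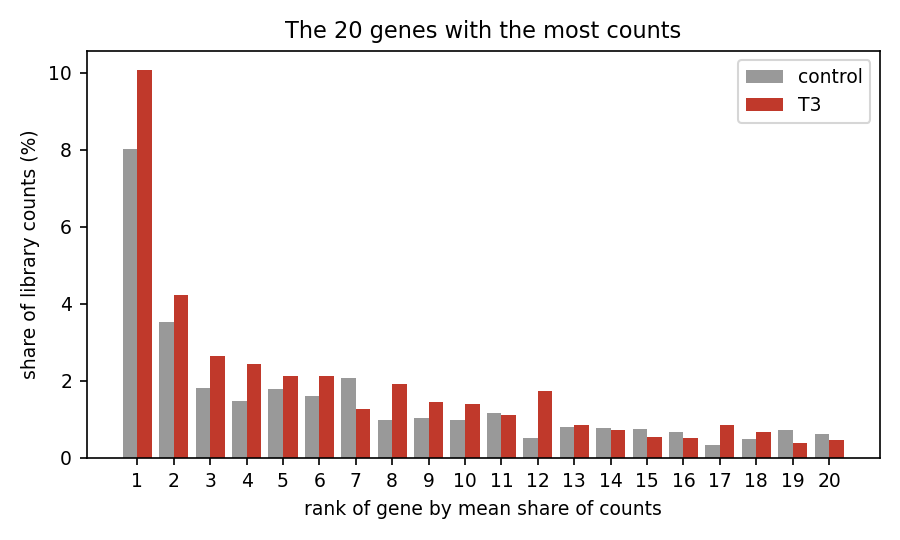
Share of all gene counts in the control library (grey bars) and the T3 library (red bars), in percent, for the 20 genes with the highest mean share, ordered by rank. The first gene took 8.03% of the control and 10.1% of the T3 counts, and the gene of rank 12 went from 0.508% to 1.75%.

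Outside the 20 most abundant genes, the median lay on the other side. The remaining 210 genes with at least 5000 counts over both libraries had a median log2 ratio of -0.27, although 8 of them were higher and 6 lower beyond 2-fold. Their median was between -0.34 and -0.18 under the 5 scalings. Of less abundant genes, the 584 genes with 1000 to 5000 counts had a median of -0.10. The medians were close to 0 at lower abundance, at -0.02 for 2815 genes with 200 to 500 counts and 0.02 for 3531 genes with 100 to 200 counts. Among genes of 10 to 50 counts the median was 0.04. Scaling by totals moved the median of all genes by -0.07 and leaving out the 20 most abundant genes moved it by 0.09. The medians of -0.02, 0.02 and 0.04 therefore have no direction that holds under every scaling.

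The spread of the ratios holds counting error together with any effect of the treatment and any difference between fish and between library preparations. Beyond counting error, these cannot be separated here. For genes with 200 to 500 counts the robust standard deviation of the log2 ratios across genes was 0.37, against 0.17 from counting alone. For genes with 10 to 50 counts the corresponding values were 0.75 and 0.57. They were 0.40 and 0.07 for genes with 1000 to 5000 counts, and 0.34 and 0.02 for genes with at least 5000 counts. Counting error was thus a small part of the spread among abundant genes. The ratio of an abundant gene can therefore lie beyond counting error and still within the spread across genes. By their intervals, 8060 of the 17301 genes (46.6%) had a counting interval that lay wholly within 2-fold of equal abundance. For a further 9004 genes the interval reached past 2-fold without excluding it, and a 2-fold difference could not be decided at this depth.

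Genes with short coding sequences were lower in the T3 library than genes with long ones. Among 8083 genes with at least 100 counts, the 1015 genes with coding lengths of 126 to 597 nt had a median log2 ratio of -0.14 (95% bootstrap interval over genes, -0.18 to -0.11). The 1009 genes of 3948 to 102705 nt had a median of 0.09 (0.07 to 0.11). These intervals resample genes as if they were independent and hold no variation between fish or libraries. Spearman's rho between coding length and log2 ratio was 0.14 across genes. By count, 20 of the shortest genes were lower and 6 higher beyond 2-fold, against 6 lower and 6 higher among the longest. These counts were not graded by length, as 10 genes were lower and 3 higher in the class of 2661 to 3945 nt. The difference between the shortest and longest class does not depend on the scaling, which multiplies every gene of a library by the same factor.

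**Figure D3:**
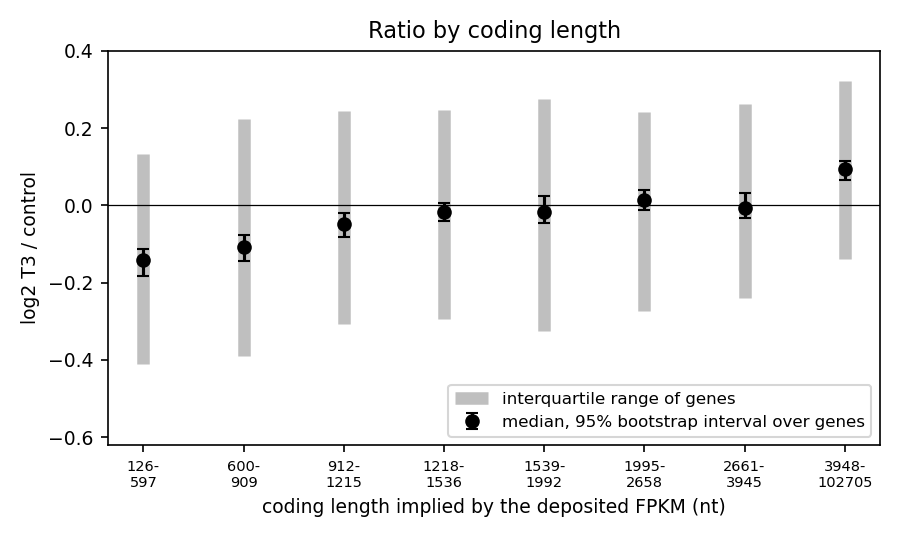
Log2 ratio of the T3 library to the control library (y axis) in 8 classes of coding length implied by the deposited FPKM (x axis, nt), for 8083 genes with at least 100 counts. Black points are class medians with 95% bootstrap intervals over genes and grey bars span the interquartile range of genes; the median goes from -0.14 in the shortest to 0.09 in the longest class.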

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

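The T3 library thinned to the control depth, the coding length trend removed, and ratios centred on the median gene were alternatives chosen after seeing the data; the others were planned. Of 14 alternatives, 9 left the count of higher genes (79) and 10 the count of lower genes (158) within 1.5 times, and lower genes outnumbered higher ones in all 14. These included each scaling: 80 higher and 158 lower with DESeq2 size factors, 86 and 151 with the upper quartile, 66 and 187 with library totals, and 98 and 129 without the 20 most abundant genes. The 14 alternatives reuse the same 2 libraries and are not independent checks. Some could change little, such as no count minimum (79 higher and 160 lower) and centring on the median gene (79 and 159). The rule for a call mattered most. The point ratio without its interval gave 993 higher and 1065 lower genes, an interval beyond 1.5-fold gave 279 and 457, and one beyond 4-fold gave 7 and 9. On the deposited FPKM, without an interval, 47 genes were higher and 113 lower with 1 added, and 281 and 650 with 0.1 added. A larger pseudocount shrinks the ratios of low genes. The FPKM are also scaled by library totals, which by themselves gave more lower and fewer higher genes than TMM. Alternatives for the gene list medians were not run, since no member of a list could be identified by ID. No paired analysis was possible because each group has 1 library, and no library could be left out for the same reason. Depth limits the comparison to larger differences: 9004 of 17301 genes could not be placed within or beyond 2-fold.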

Other observations

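The tests of scaling by abundant genes, of a graded length effect and of consecutive IDs were made after the result was seen. So were the look at the neighbours of GS_000805 and the choice of the abundance band with its split at 1000 nt. The tests of depth, of the coding length trend behind the calls and of abundance behind the length trend were set before their results were seen.

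A band of abundant genes was shifted downward together in the T3 library. Its genes belong to the 210 genes with at least 5000 counts outside the 20 most abundant, and they also enter the coding length classes. The band is therefore not a result separate from the lower medians given for those sets. Between 10 and 12 on the log2 scaled CPM axis lay 114 genes, and 78 of them had coding lengths under 1000 nt (median 548 nt). These 78 had a median log2 ratio of -0.32 with a robust standard deviation of 0.11 across genes, and 70 of the 78 were lower in the T3 library. The 36 genes of the band with longer coding sequences had a median of -0.17 and a robust standard deviation of 0.35, and 22 of the 36 were lower. The median of the 78 genes stayed below 0 under all 5 scalings, from -0.39 with library totals to -0.23 without the 20 most abundant genes. Which genes these are was not resolved, as the IDs carry no names.

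The lower gene ranked first, GS_000805, had neighbours in the ID order with few or no counts in the T3 library. The IDs directly before and after it held 5 and 10 counts in the control library and 0 in the T3 library, and the first of these was under the minimum of 10 counts. The second ID after it held 15 and 1 counts. The next ID on either side of these held 15 and 16 counts before, and 99 and 92 after. These IDs were looked at after this gene's values were seen, and no chance value is given.

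The log2 ratios of consecutive IDs were slightly more alike than those of shuffled IDs. Across 3382 pairs of consecutive IDs with at least 100 counts each, Spearman's rho of the log2 ratios was 0.064, outside the central 95% of 100000 shuffles of the IDs (-0.034 to 0.034) and under their maximum of 0.070. It was 0.049, 0.011, 0.027 and 0.0022 for IDs 2, 5, 10 and 50 apart, and Pearson's r was 0.081 for consecutive IDs and 0.024 for IDs 2 apart. Shuffles were run for consecutive IDs alone. Among genes beyond 2-fold, 5 consecutive pairs went the same way and 1 the opposite way, where shuffling gave a mean of 1.47 same-way pairs and a 97.5th percentile of 4. Of the 5 pairs, 2 lie among GS_000805 and the 2 IDs after it, and the 3 pairs left without them lie within the shuffled range. A hypothesis is that consecutive IDs may mark genes related in position or sequence, which regulation, shared reads or a structural difference between fish could each link. The test does not separate these, and whether the ID order follows the genome is not given in the sources used here.

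Lower genes outnumbered higher genes by 158 to 79. They did so in every class of counts under 5000, from 26 to 6 at 50 to 100 counts to 28 to 22 at 200 to 500. At 5000 counts or more the direction was reversed, with 6 lower and 11 higher. The size of the excess depends on the calling rule. It was small by the point ratio alone (1065 lower, 993 higher) and rested on few genes for intervals beyond 4-fold (9 and 7). It was 457 to 279 for intervals beyond 1.5-fold and 131 to 68 with a minimum of 50 counts. On the deposited FPKM it was 113 to 47 with 1 added and 650 to 281 with 0.1 added. The FPKM are scaled by library totals and not by TMM, so scaling changed there as well as the rule. The greater depth of the T3 library did not account for the excess. The ratio of lower to higher genes was 1.92 with that library thinned to the control total (1.79 to 2.08 over 20 draws). The coding length trend did not account for it either, with a ratio of 1.95 after its removal. Scaling stays open: the ratio fell to 1.32 with the 20 most abundant genes left out, but was 1.98 with the median of ratios of DESeq2, and nothing in the table says which scaling is right. A response to T3 may also underlie the excess, and with 1 library per group it was not tested.

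The lower ratio of genes with short coding sequences was not a by-product of their total counts. Within 4 classes of counts between 100 and 5000, the smallest Spearman's rho was 0.11. A gene's counts can rise with its length as well as its abundance, so abundance per length was not held fixed. The test therefore cannot exclude a difference in abundance per length. A graded length effect between the 2 libraries, as differences in fragmentation or RNA integrity could give, cannot be told apart from a difference in which short genes the fish expressed. The class medians went up in 5 of 7 steps, and the 2 steps down lay within the bootstrap intervals. Each library is its own group, so no value here separates library preparation from treatment.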
